A study of Caenorhabditis elegans with 26 samples.

How the data were processed

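Small RNAs of whole worms were cloned from 26 libraries in 13 groups of 2. Per the labels' protocols, worms were lysed, small RNAs were extracted with Trizol and treated with PIR-1, a phosphatase that trims the triphosphate of secondary small RNAs so that linkers can be joined, and linkers were then ligated to both ends before reverse transcription, PCR and size selection on native polyacrylamide gels. Per the submitters' processing notes, cutadapt 4.9 and Bowtie 1.3.1 were used with the WBcel235 genome, with no role or setting given. The counting program, whether strand was used, and the treatment of multi-mapping reads and of PCR duplicates are not given in the sources used here. Reads of a gene, of an overlapping gene on the other strand and of near-identical copies can therefore not be told apart. This bears on pseudogenes, F-box genes and vitellogenin genes among others.

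The authors deposited a table of whole-number read counts per transcript for the 6 libraries without a tethered protein, and a table with 1 value per library of reads mapped to the transgene for the 20 tethered libraries, whose whole-number counts are per the file headers reads mapped and whose library totals and scaling are not given in the sources used here. The count table listed 34324 identifiers. Of these, 33755 matched a transcript name and 190 a sequence name of the WBcel235 annotation, and 379 matched none. 1 identifier was blank and held 0 reads. Transcripts were summed to 22271 genes, 19980 of them protein-coding and 1918 pseudogenes, and 205 names shared by several genes were replaced by their RefSeq names. The table held no microRNA, piRNA or rRNA genes, so these lists had 0 members.

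Genes were tested with edgeR 4.0.16 in R 4.3.3 by its quasi-likelihood F test (robust fit, TMM factors), 1 coefficient per group, on genes kept by its expression filter (minimum count 10, minimum total 15), and p-values were adjusted by the Benjamini-Hochberg method at 0.05. The fit was meant for all 26 libraries, but gene counts were analysed for 6, so it held 3 groups and 3 residual degrees of freedom. It tested 5312 genes with 98.3% of the reads, and the coefficient of biological variation was 0.0401. TMM factors were 0.582 and 0.593 in WT, 1.35 and 1.34 in mut-16(DE6R) and 1.26 and 1.27 in rde-3 mut-16(DE6R). CPM values use these factors. The SE given with a log2 fold change is its absolute value divided by the square root of the F statistic. It therefore restates the p-value and is unsure for genes with few reads. All fold changes are therefore relative to the bulk of genes, and no spike-in is named in the sources used here. Genome-wide tests of tethered strains, the test of mutator-dependent genes in them and the comparison of tethered wild type with WT were not analysed here.

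Gene lists were fixed before the data were examined: mutator complex, Argonaute, germ granule, RNAi cofactor, ERGO-1 target, germline division, sperm, histone, ribosomal protein, muscle, intestine, cuticle, neuron, pseudogene and transgene part genes. Lists with at least 5 tested genes (14 lists, 42 tests) were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, with an estimated correlation, and with fry. Of the 42 tests, 19 passed with the preset correlation, 0 with an estimated one (10 at an unadjusted p under 0.05; lowest adjusted p 0.115) and 31 with fry, which asks whether a list moves on balance 1 way without setting it against other genes. With an estimated correlation camera works on the 3 residual degrees of freedom, and with a preset one on about as many as genes. Estimated correlations of intestine (−0.042), cuticle (−0.134) and muscle genes (−0.2) lay under the preset 0.01. In rde-3 mut-16(DE6R) against WT, camera's unadjusted p for cuticle genes still went from 0.00126 to 0.045. The 0 of 42 therefore does not show that correlation within lists undoes these results. Some lists overlap: of 11 tested ERGO-1 targets 5 are also pseudogenes, and of 13 tested Argonaute genes 1 is. Germline division holds 3 of the 5 tested transgene part genes. Results of such lists are not independent of each other. Muscle, intestine, cuticle and neuron genes serve as markers of tissues outside the germline. The muscle, intestine and cuticle lists hold 17, 18 and 168 genes, of which 5, 10 and 7 were tested. The expression filter keeps a gene that is high in any 1 group. Members with few reads in WT were thus tested only through the mutant libraries, and their rise against WT was set by the filter. Counts, medians and set tests of lists with such members are biased upward.

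Named genes followed a rule fixed before the data were examined: the genes of the perturbed or tethered proteins; the 10 largest rises and 10 largest falls per comparison among genes with an adjusted p under 0.05, at least 5 CPM in the higher group and no overlap between libraries; and up to 3 members with the smallest p of each list that passed. Other list members are named because they show what a list holds and were picked after their values were seen. Genes with 0 reads in a group get a lower bound against a floor of 3 counts over the group, and genes with 1 to 3 reads get the ratio of summed reads with a 95% interval for counting error. Transgene reads were compared as ratios of means with such intervals, by an exact 2-sided permutation test per pair of strains and by a permutation test with 100000 resamples over all strains, with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

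Totals per library differed up to 3.05-fold. Replicates differed by more than counting noise in each group. The chi-square per degree of freedom was 1.54 in WT (1.31 without F56H9.8), 1.11 in mut-16(DE6R) and 1.13 in rde-3 mut-16(DE6R). All 6 libraries were counted separately, but such an excess does not tell separate cultures from separate preparations of one RNA. The procedure was tested on simulated counts with the totals of these 6 libraries, the same mean per gene in all groups and 200 changed genes. The data held far more calls, 2270 to 3439 per comparison, with splits that moved with scaling. Shares from the simulation therefore hold for its own setting and do not give the error rate of the calls in the data. In mut-16(DE6R) against WT (4744 genes), 42%, 66%, 96% and 96% of genes changed 1.5-, 2-, 4- and 8-fold were recovered, and 4.46% of calls were unchanged genes. In rde-3 mut-16(DE6R) against WT (4776 genes) the shares were 30%, 58%, 92% and 84%, with 2.22% of calls on unchanged genes, and in the double mutant against mut-16(DE6R) (4753 genes) 28%, 54%, 92% and 96%, with 8.16%.

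The alternatives tried were DESeq2 1.42.0, median-ratio factors, library totals, no filter on low counts, a replicate block, a fit of only the 2 groups compared and leaving out each library. Upper quartile factors, totals without F56H9.8, scaling to mitochondrial reads and counts of transcripts without summing were added after seeing the data.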

Results

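Small RNAs of whole Caenorhabditis elegans worms were cloned and sequenced from 13 groups of 2 libraries. Genotypes without a tethered protein were profiled over the annotated genes: wild type (WT), rde-3 mut-16(DE6R) and mut-16(DE6R), with 6 libraries in all. MUT-16 is the scaffold protein of the mutator foci, perinuclear granules of the germline in which secondary small RNAs of the 22G class are made on target transcripts. RDE-3, also called MUT-2, is a nucleotidyltransferase that adds tails of U and G to RNAs that then serve as templates for that synthesis. The other 20 libraries came from 10 strains of a tethering assay, in which a protein is fused to lambdaN, a phage peptide that binds the boxB RNA hairpin, and so is brought to a transcript that carries boxB. For these libraries the reads mapped to the transgene were analysed, 1 value per library. The labels do not say whether the 2 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. The fit moderates the spread of each gene with that of all genes, since 1 gene has only 3 residual degrees of freedom. Very small p-values therefore rest on this pooled spread and not on the libraries of that gene alone.

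Counted reads summed to 1149904 and 1359593 in WT, 620047 and 1571194 in mut-16(DE6R), and 515300 and 584502 in rde-3 mut-16(DE6R). A single gene of chromosome V, F56H9.8 (12644800 to 12646679 in WBcel235), held 50.6 ± 1.51% of the reads in WT, 37.6 ± 0.0538% in mut-16(DE6R) and 55.5 ± 0.0231% in rde-3 mut-16(DE6R) (SD, n = 2). It is overlapped on the opposite strand by gpa-9, and all of its reads were listed under 1 of its 3 transcripts. Whether these reads are small RNAs of the locus, fragments of another RNA or a product of the mapping is open, since the sources used here do not tell. Reads on the 12 mitochondrial genes made up 2.31 ± 0.152%, 4.35 ± 0.0662% and 4.49 ± 0.132% (SD, n = 2) in the same order. Among the remaining reads, pseudogenes took 18.4 ± 0.0349% in WT, 10.3 ± 0.00508% in mut-16(DE6R) and 2.54 ± 0.0833% in rde-3 mut-16(DE6R) (SD, n = 2). Loci on X held 9.48 ± 0.0733%, 9.11 ± 0.0148% and 3.04 ± 0.0103% of those reads (SD, n = 2). These shares were not tested: with 2 libraries against 2, an exact 2-sided permutation test cannot go below p = 0.333.

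**Figure D1:**
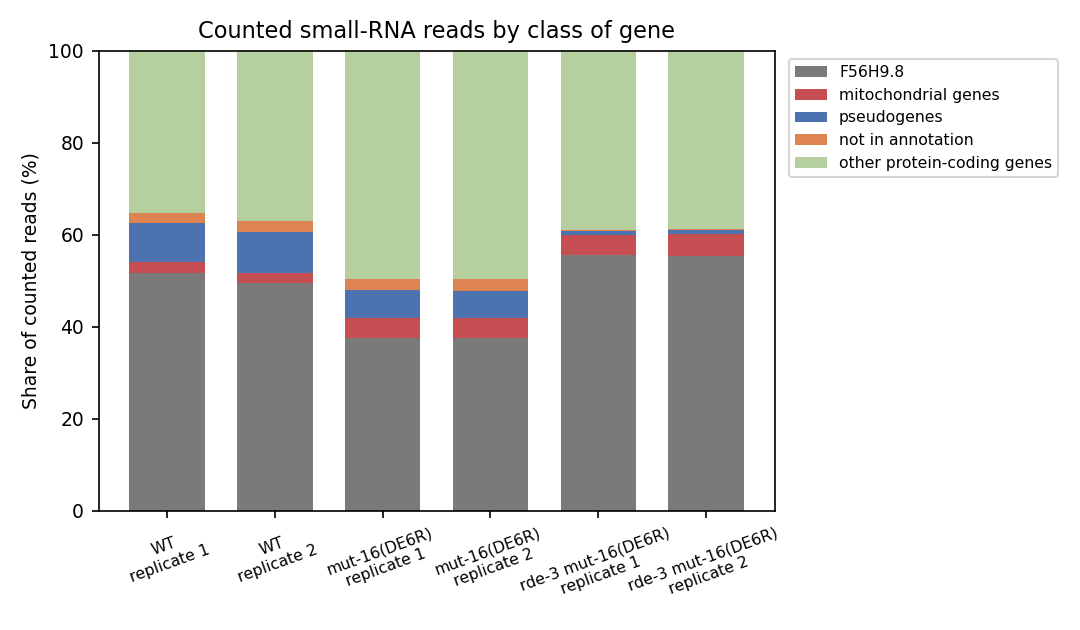
Share of counted small-RNA reads (percent, stacked bars) taken by F56H9.8, mitochondrial genes, pseudogenes, loci outside the annotation and other protein-coding genes in each of the 6 untethered libraries. Pseudogene reads made up 8.65% of all reads in WT, 6.00% in mut-16(DE6R) and 1.02% in rde-3 mut-16(DE6R) on average.

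Reads on the perturbed genes themselves were few. At mut-16 (chromosome I, 10080159 to 10085765) the libraries held 7.47 and 2.48 CPM in WT, 2.38 and 2.38 in mut-16(DE6R), and 10.8 and 10.8 in rde-3 mut-16(DE6R), from 7, 7 and 15 reads per group. At mut-2, the gene of RDE-3, the groups held 1, 7 and 2 reads and the gene was not tested. Small-RNA reads on a gene are not its mRNA, so these values do not check the genotypes.

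The first comparison asked which genes carried more or fewer small-RNA reads with the mut-16(DE6R) allele. In mut-16(DE6R) worms, reads fell at 10 of 11 tested targets of the Argonaute ERGO-1 and at 228 of 286 tested pseudogenes. They rose at 7 of 10 tested intestine genes and 15 of 35 tested germline division genes. These lists passed as sets with camera's preset correlation, but not with an estimated correlation, which leaves camera only 3 degrees of freedom. E01G4.5, an ERGO-1 target (chromosome II, 13472401 to 13473995), had 4344 ± 31.7 CPM in WT and 398 ± 32.7 CPM in mut-16(DE6R) (SD, n = 2 each), a log2 fold change of −3.47 (SE 0.07). The pseudogene C01G6.10 (chromosome II, 9289506 to 9291539) had 3183 ± 60.2 and 192 ± 6.55 CPM (SD, n = 2 each), a log2 fold change of −4.04 (SE 0.08). In the other direction, vit-2 (X, 5101042 to 5106169), a vitellogenin gene of the intestine, had 27.5 ± 5.00 CPM in WT and 121 ± 7.23 CPM in mut-16(DE6R) (SD, n = 2 each), a log2 fold change of 2.13 (SE 0.21). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 1173 genes rose and 1944 fell among 5312 tested, of which 469 and 1504 changed at least 2-fold.

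Of the 11 tested ERGO-1 targets, 10 fell and none rose, also 10 adjusted over the list alone. The list median was −1.67 on the log2 scale (camera adjusted p = 6.72e-04; adjusted p = 0.282 with an estimated correlation). Examples were F39E9.7 (−2.13, SE 0.07), E01G4.7 (−1.97, SE 0.07) and H16D19.4 (−1.42, SE 0.12). Among 286 tested pseudogenes, 14 rose, 228 fell and 44 did not pass, or 15 and 232 adjusted over the list alone. Their median was −1.66 (camera adjusted p = 3.49e-15; adjusted p = 0.115 with an estimated correlation). C06C3.5 (−6.43, SE 0.14) and F32A11.5 (−4.33, SE 0.09) were among those that fell. In the intestine list 7 of 10 tested genes rose, also 7 adjusted over the list alone. The median was 2.17, or 1.66 with genes at 0 in WT at their bound (camera adjusted p = 3.06e-04; adjusted p = 0.176 with an estimated correlation). The vitellogenin genes vit-1 (2.49, SE 0.34), vit-2 and vit-5 (2.23, SE 0.35) were among those higher, and their near-identical sequences leave open how reads were shared between them. Meiosis and cell division genes of the germline, a class known to carry 22G RNAs of the Argonaute CSR-1, had 15 of 35 tested genes higher and none lower, also 15 adjusted over the list alone. Their median was 0.29 (camera adjusted p = 4.74e-04; adjusted p = 0.189 with an estimated correlation), with the kinetochore genes hcp-4 (0.68, SE 0.09) and bub-1 (0.64, SE 0.09) and the spindle gene zyg-9 (0.69, SE 0.09) as examples. Ribosomal protein genes had a median of 0.40 with 6 higher, 3 lower and 42 that did not pass, or 2 and 2 adjusted over the list alone (camera adjusted p = 8.94e-03; adjusted p = 0.306 with an estimated correlation). Calls of 3 of these genes rested on single libraries: without WT library 1 the log2 fold changes of rpl-9 and rpl-27 were 1.06 and 0.79, without WT library 2 that of rps-14 was 0.77, without mut-16(DE6R) library 2 that of rpl-9 was 1.37, and none of these passed. DESeq2 called none of these 3 genes.

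The other lists did not pass as sets, although members changed. The collagen and cuticle list had 4 of 7 genes lower, also 4 adjusted over the list alone (median −0.95, but 0.24 scaled to library totals; camera adjusted p = 0.284). Among them col-60 was at −6.32 (SE 0.31) and col-71 at −0.95 (SE 0.10). Histone genes had 1 higher and 4 lower of 7 (median −0.44, above 0 scaled to library totals with or without F56H9.8; camera adjusted p = 0.392). The linker histone gene his-24 fell by 0.44 on the log2 scale (SE 0.07) and his-72 rose (1.49, SE 0.31). Mutator complex genes had 1 higher and 5 lower of 9 (median −0.69, above 0 scaled to library totals with or without F56H9.8; camera adjusted p = 0.334). The RNA-dependent RNA polymerase gene rrf-1 was among those that fell (−1.42, SE 0.27). Argonaute genes had 4 higher and 5 lower of 13 (median −0.25, above 0 under 4 other scalings; camera adjusted p = 0.782 upwards, against the sign of the median and mean). They included sago-1 (−1.49, SE 0.29) and wago-4 (0.52, SE 0.09). Germ granule genes had 5 higher and 2 lower of 20 (median 0.12; camera adjusted p = 0.176, but 0.0244 scaled to library totals, with a range of 0.0244 to 0.469 over the alternatives). The P granule component genes meg-1 (1.70, SE 0.26) and meg-2 (2.07, SE 0.25) rose. RNAi cofactor genes had 4 higher and 5 lower of 20 (median 0.09, mean −0.08; camera adjusted p = 0.489). Reads fell at eri-6 (−1.06, SE 0.07) and at the double-stranded RNA channel gene sid-1 (−0.99, SE 0.08). Muscle genes had 2 higher of 5 (median 0.23; camera adjusted p = 0.196). Sperm genes had 2 lower of 7 (median −0.45, but 0.72 scaled to library totals and 0.48 without F56H9.8; camera adjusted p = 0.619). Genes often used as parts of transgenes had 1 higher of 5, pie-1 at 0.79 with an SE of 0.26 (median 0.34; camera adjusted p = 0.129). Adjusted over the list alone, 5 Argonaute genes rose and the counts of these other lists did not move. Neuron genes had 4 tested members, too few for a set test: egl-21 (−1.75, SE 0.15), ida-1 (−1.09, SE 0.24) and unc-17 fell and snb-1 (1.67, SE 0.35) rose. At unc-17 the reads were 3 against 59, 39.2-fold lower (counting interval 12.8 to 195).

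Some genes that rose had no read in WT, so that only a bound on their fold can be given. The carboxylesterase gene cest-32 held 82 reads in mut-16(DE6R) against 0, at least 13.7-fold higher against a floor of 3 counts over the group. On X, yap-1, the gene of the worm Yes-associated protein, held 55 against 0, at least 9.20-fold higher. At R193.3 on X the ratio was 25.3 (counting interval 6.84 to 212) from 101 and 2 reads, and at idh-2, an isocitrate dehydrogenase gene, 24.6 (4.21 to 991) from 49 and 1. Among genes that fell, H14E04.3 held 0 reads against 76, at least 50.5-fold lower, and djr-1.2 held 1 against 210, 419-fold lower (counting interval 74.3 to 16608). The hydrolase-family gene abhd-14 fell by 6.49 on the log2 scale (SE 0.21; edgeR's quasi-likelihood test with Benjamini-Hochberg adjusted p = 6.99e-201). Of the genes of tethered proteins, rde-1 (0.47, SE 0.15), wago-1 (0.31, SE 0.14) and ppw-2, also called wago-3 (0.31, SE 0.09), rose. The gene mut-14 was at 0.01 (SE 0.12) and did not pass, but rose with library totals (1.20), totals without F56H9.8 (0.87) and upper quartiles (0.41). Neither did mut-16 pass (−0.96, SE 0.79), and pgl-3 held 6 and 8 reads and was not tested. The Argonaute gene prg-1 fell by 0.25 on the log2 scale (SE 0.07), a direction that turned under every scaling tried other than median ratios and with no filter on low counts, and it did not pass in a fit of only the 2 groups. The rise of rde-1 did not pass without WT library 1 (0.30). That of wago-1 did not pass without any 1 library: the estimates were 0.30 and 0.26 without WT library 1 or 2, and 0.27 and 0.39 without mut-16(DE6R) library 1 or 2. DESeq2 called neither.

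The median log2 fold change of all genes was −0.09 in this comparison, and scaling moved it to 1.09 with library totals, 0.74 with totals without F56H9.8, 0.18 with mitochondrial reads and 0.30 with upper quartiles. The split of 1173 higher and 1944 lower became 3394 and 1005, 2925 and 1270, 1731 and 1640, and 2107 and 1586 under the same 4 scalings, and 482 and 1571 in DESeq2. The directions of the list medians given for ERGO-1 targets, pseudogenes, intestine, germline division and ribosomal protein genes held under all 6 scalings, but the counts of members did not. Germline division genes went from 15 higher to 35, 34, 26 and 31 under the same 4 scalings, and with library totals ribosomal protein genes had 42 higher and 0 lower, germ granule genes 19 and 0, pseudogenes 61 and 147, and ERGO-1 targets 2 and 6. The lists that did not pass moved too: with library totals the genes higher and lower were 17 and 0 for RNAi cofactors, 11 and 0 for Argonautes, 3 and 0 for the mutator complex, 4 and 2 for histones, 4 and 2 for collagens and 3 and 1 for sperm. All 5 transgene part genes rose under each of these 4 scalings.

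The second comparison set rde-3 mut-16(DE6R), in which both genes are mutated, against WT. Of the tested genes, reads fell at 11 of 11 ERGO-1 targets, 247 of 286 pseudogenes and 7 of 7 collagen genes. They rose at 10 of 10 intestine, 4 of 5 muscle and 25 of 35 germline division genes. As sets, these lists passed with camera's preset correlation, but not with an estimated correlation. E01G4.5 had 99.7 ± 11.2 CPM in rde-3 mut-16(DE6R) (SD, n = 2) against 4344 ± 31.7 CPM in WT, a log2 fold change of −5.45 (SE 0.10). The collagen gene col-71 (chromosome II, 3500077 to 3502570) had 430 ± 18.9 CPM in WT and 3.47 ± 2.73 CPM in the double mutant (SD, n = 2 each), a log2 fold change of −6.86 (SE 0.26). At unc-54, which encodes a myosin heavy chain of body wall muscle (chromosome I, 14855901 to 14863482), reads rose from 19.6 ± 0.285 to 142 ± 12.1 CPM (SD, n = 2 each), a log2 fold change of 2.84 (SE 0.25). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 1424 genes rose and 2015 fell of 5312 tested, 569 and 1843 of them at least 2-fold.

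All 11 tested ERGO-1 targets fell, also 11 adjusted over the list alone. Their median was −5.45, or −5.29 with genes at 0 in the double mutant at their bound (camera adjusted p = 4.14e-05; adjusted p = 0.239 with an estimated correlation). F39E9.7 fell by 5.46 (SE 0.10) and E01G4.7 by 5.28 (SE 0.11) on the log2 scale. Pseudogenes counted 8 higher, 247 lower and 31 that did not pass, or 8 and 248 adjusted over the list alone. The median was −4.61, or −4.37 with such genes at their bound (camera adjusted p = 5.77e-21; adjusted p = 0.115 with an estimated correlation). C01G6.10 (−5.90, SE 0.11) and C18H2.9 (−5.46, SE 0.14) were examples. The 7 collagen genes tested all fell, also 7 adjusted over the list alone (median −5.85, or −4.73 with such genes at their bound; camera adjusted p = 3.54e-03; adjusted p = 0.189 with an estimated correlation). One of them was col-60 (−5.85, SE 0.36). At col-111 the double mutant held 3 reads against 225, 70.7-fold lower (counting interval 23.9 to 345). The 7 tested genes come from a cuticle list of 168, most of which had few reads in WT. Summed over the 157 under 5 CPM in WT, reads were 117 against 130, 0.955 times WT after scaling (counting interval 0.737 to 1.24). All 10 tested intestine genes rose, also 10 adjusted over the list alone. Their median was 3.06, or 2.90 with such genes at their bound (camera adjusted p = 2.49e-05; adjusted p = 0.161 with an estimated correlation). They included vit-2 (3.24, SE 0.20), vit-1 (3.78, SE 0.30) and vit-5 (3.14, SE 0.33). Members with few WT reads, such as cpr-1 (0) and vit-4 (2), passed the filter only through mutant libraries, so their direction was set by it. Over all 18 genes, unfiltered, the share of reads outside F56H9.8 and mitochondrial genes was 0.00952% in WT and 0.208% in rde-3 mut-16(DE6R). Muscle genes had 4 of 5 higher, or 5 adjusted over the list alone (median 2.18; camera adjusted p = 5.72e-03, but 0.0769 scaled to library totals, with a range of 1.51e-04 to 0.202; adjusted p = 0.202 with an estimated correlation). Another myosin gene, myo-3, was at 2.18 (SE 0.51), and the troponin gene tnt-2 at a ratio of 10.3 (counting interval 3.18 to 52.6) from 29 and 3 reads. Germline division genes had 25 higher, 2 lower and 8 that did not pass of 35, also 25 and 2 adjusted over the list alone. The list median was 0.62 (camera adjusted p = 4.14e-05; adjusted p = 0.180 with an estimated correlation). Rises included hcp-4 (0.99, SE 0.10) and the meiotic chromosome axis gene htp-3 (0.81, SE 0.12). Ribosomal protein genes had 11 higher, 2 lower and 38 that did not pass, or 6 and 2 adjusted over the list alone (median 0.66; camera adjusted p = 7.31e-04; adjusted p = 0.282 with an estimated correlation). The rises of rpl-4 (1.53, SE 0.44), rpl-14 (1.77, SE 0.61) and rpl-5 (0.91, SE 0.31) did not pass without single libraries. Without rde-3 mut-16(DE6R) library 1 the estimates were 0.80 for rpl-4 and 0.75 for rpl-5. They were 1.66 for rpl-14 without library 2 of that group, and 1.39 for rpl-14 and 0.72 for rpl-5 without WT library 2. DESeq2 called neither rpl-14 nor rpl-5.

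Lists that did not pass in this comparison held members with large falls. Histone genes had 1 higher and 5 lower of 7 (median −3.15; camera adjusted p = 0.155), with his-24 at −5.60 (SE 0.13) and his-35 at −4.52 (SE 0.38). RNAi cofactor genes had 5 higher and 5 lower of 20 (median 0.05, mean −0.64; camera adjusted p = 0.560). Here eri-6 (−5.01, SE 0.11) and sid-1 (−4.01, SE 0.14) fell and the Dicer gene dcr-1 (0.89, SE 0.12) rose. Argonaute genes had 5 higher and 4 lower of 13 (median 0.17, mean −0.37; camera adjusted p = 0.320). In that list vsra-1 fell by 2.34 on the log2 scale (SE 0.38) and wago-4 rose (0.68, SE 0.09). Mutator complex genes had 3 higher and 4 lower of 9 (median −0.41, tested upwards by camera and above 0 with library totals, with totals without F56H9.8 and with upper quartiles; camera adjusted p = 0.829). The helicase gene smut-1 fell (−1.92, SE 0.29) and mut-7 rose (0.70, SE 0.11). Sperm genes had 4 lower of 7 (median −2.15, but 0.63 without F56H9.8 in the totals; camera adjusted p = 0.247). Leaving F56H9.8 out of the totals also changed which genes were tested (5339 in all), so that turn is not one of scaling alone. At spe-51 the reads were 2 against 133, 62.7-fold lower (counting interval 17.0 to 523). Germ granule genes had 8 higher and 3 lower of 20 (median 0.18; camera adjusted p = 0.121, but 0.0192 scaled to library totals, with a range of 0.0192 to 0.434), such as the helicase gene cgh-1 (1.03, SE 0.14). Transgene part genes had 4 higher and 1 lower of 5 (median 1.04; camera adjusted p = 0.0636), such as mex-5 (1.17, SE 0.18). Adjusted over the list alone, the counts of these 7 lists were the same. Of the 4 neuron genes, egl-21 (−5.35, SE 0.30), ida-1 and unc-17 fell and snb-1 did not pass (0.37, SE 0.48). Reads were 0 against 95 at ida-1, at least 29.9-fold lower, and 1 against 59 at unc-17, 55.6-fold lower (counting interval 9.60 to 2234).

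Here too, genes with no read in WT rose: the aspartyl protease gene asp-2 held 30 reads in the double mutant, at least 10.6-fold higher. The cathepsin B-like gene cpr-1 held 19, at least 6.72-fold higher, and emb-9, which encodes a type IV collagen of basement membranes, held 18, at least 6.36-fold higher. At asp-3, another aspartyl protease gene, the ratio was 35.0 (counting interval 9.31 to 295) from 66 and 2 reads. Falls to 0 included M03A1.8 and C32D5.12 on chromosome II, with 0 reads against 154 and 152, at least 48.4-fold and 47.8-fold lower. The F-box gene fbxa-53 (0 against 141, at least 44.3-fold lower) and the sex determination gene xol-1 (0 against 114, at least 35.8-fold lower) also lost their reads. Of the genes of tethered proteins, wago-1 (1.21, SE 0.13), mut-14 (0.75, SE 0.12), ppw-2 (0.57, SE 0.09) and rde-1 (0.53, SE 0.17) rose, and mut-16 did not pass (1.16, SE 0.66) except with library totals, totals without F56H9.8 or upper quartiles. The fall of prg-1 (−0.21, SE 0.08) turned with library totals, with totals without F56H9.8 and with upper quartiles, and did not pass with mitochondrial reads, with no filter or without rde-3 mut-16(DE6R) library 2 (−0.16). Without that library the rise of rde-1 did not pass either (0.39), nor without WT library 1 (0.35) or in DESeq2. The median of all genes moved from −0.03 to 1.06 with library totals, 1.23 without F56H9.8, 0.10 with mitochondrial reads and 0.50 with upper quartiles. The split of 1424 and 2015 became 2944 and 1544 with library totals, 3109 and 1523 without F56H9.8, 2369 and 1742 with upper quartiles, and 747 and 1806 in DESeq2. With library totals, ribosomal protein genes had 45 higher and 0 lower, germ granule genes 18 and 1, germline division genes 35 and 0, pseudogenes 29 and 226, Argonaute genes 10 and 2, RNAi cofactor genes 14 and 5, and mutator complex genes 5 and 1.

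The third comparison set rde-3 mut-16(DE6R) against mut-16(DE6R), which asks what changed when rde-3 was mutated as well. Of the tested genes, reads fell at 10 of 11 ERGO-1 targets, 187 of 286 pseudogenes and 5 of 7 collagen genes. They rose at 9 of 10 intestine and 5 of 5 muscle genes. Again these lists passed as sets with the preset correlation of camera, but not with an estimated correlation. F39E9.7 (chromosome II, 3306144 to 3307505) went from 1029 ± 3.62 CPM in mut-16(DE6R) to 102 ± 7.40 CPM in the double mutant (SD, n = 2 each), a log2 fold change of −3.33 (SE 0.11). The pseudogene Y59H11AR.6 went from 2001 ± 4.87 to 109 ± 13.3 CPM (SD, n = 2 each), a log2 fold change of −4.18 (SE 0.10). At vit-2 the groups had 121 ± 7.23 and 265 ± 34.5 CPM (SD, n = 2 each), a log2 fold change of 1.11 (SE 0.12). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 877 genes rose and 1393 fell, 202 and 1271 of them at least 2-fold.

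ERGO-1 targets had 10 of 11 lower, also 10 adjusted over the list alone (median −3.56, or −3.33 with genes at 0 at their bound; camera adjusted p = 8.66e-06; adjusted p = 0.218 with an estimated correlation). The targets C44B11.6 and E01G4.7 were at −5.41 (SE 0.20) and −3.31 (SE 0.12). Pseudogenes had 17 higher, 187 lower and 82 that did not pass, or 21 and 197 adjusted over the list alone. Their median was −2.46 (−2.13 with such genes at their bound; camera adjusted p = 6.74e-16; adjusted p = 0.115 with an estimated correlation). Falls included F37H8.2 (−3.42, SE 0.09) and Y39E4B.14 (−3.05, SE 0.08). Collagen genes had 5 of 7 lower, also 5 adjusted over the list alone (median −5.02, or −3.66 with such genes at their bound; camera adjusted p = 0.0183; adjusted p = 0.218 with an estimated correlation). Reads fell by 5.90 at col-71 (SE 0.30) and by 5.02 at col-157 (SE 0.38) on the log2 scale. Intestine genes had 9 of 10 higher, also 9 adjusted over the list alone (median 1.20; camera adjusted p = 5.23e-05; adjusted p = 0.161 with an estimated correlation). Further examples were vit-1 (1.28, SE 0.18) and asp-1 (1.11, SE 0.24). All 5 muscle genes rose, also 5 adjusted over the list alone (median 1.64; camera adjusted p = 1.14e-03; adjusted p = 0.187 with an estimated correlation). The estimates were 1.64 for unc-54 (SE 0.17) and 1.95 for myo-3 (SE 0.41). The troponin I gene unc-27 was at 2.59 (SE 0.63), a rise that did not pass without rde-3 mut-16(DE6R) library 2 (2.55) or in DESeq2. Germline division genes had 12 higher, 1 lower and 22 that did not pass, also 12 and 1 adjusted over the list alone. The median was 0.22 (camera adjusted p = 3.54e-03; adjusted p = 0.218 with an estimated correlation). They included mex-5 (0.90, SE 0.15), htp-3 (0.47, SE 0.10) and tac-1 (0.52, SE 0.13). The calls of htp-3 and tac-1 were absent with no filter on low counts, and that of tac-1 in DESeq2. Ribosomal protein genes had 2 higher, 2 lower and 47 that did not pass, or 0 and 1 adjusted over the list alone (median 0.40; camera adjusted p = 5.57e-03; adjusted p = 0.302 with an estimated correlation). The rises of rpl-15 (0.84, SE 0.33) and rpl-18 (0.84, SE 0.35) did not pass without single libraries. Without rde-3 mut-16(DE6R) library 2 the estimates were 0.56 and 1.00, and without mut-16(DE6R) library 1 they were 0.75 and 0.74. Without mut-16(DE6R) library 2 they were 1.02 and 1.05, and without rde-3 mut-16(DE6R) library 1 rpl-18 was at 0.68. Neither passed in DESeq2, with library totals, with mitochondrial reads or with no filter.

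Of the lists that did not pass here, histone genes had 4 of 7 lower (median −1.31; camera adjusted p = 0.0841), among them his-24 (−5.16, SE 0.13) and his-35 (−3.54, SE 0.41). Sperm genes had 4 of 7 lower (median −1.78, or −1.14 with such genes at their bound; camera adjusted p = 0.156). At spe-51 the double mutant held 2 reads against 102, 24.1-fold lower (counting interval 6.51 to 202). Mutator complex genes had 4 of 9 higher (median 0.37; camera adjusted p = 0.129), with mut-7 (0.45, SE 0.09) and nyn-1 (0.56, SE 0.13). Argonaute genes had 5 higher and 2 lower of 13 (median 0.21, mean −0.23; camera adjusted p = 0.196), with vsra-1 at −1.61 (SE 0.39). Germ granule genes had 7 higher and 5 lower of 20 (median 0.03, below 0 with library totals and mitochondrial reads; camera adjusted p = 0.203). The helicase gene cgh-1 rose (1.18, SE 0.13) and meg-2 fell (−2.32, SE 0.27). RNAi cofactor genes had 4 higher and 7 lower of 20 (median 0.03, below 0 with library totals, mitochondrial reads and median ratios; mean −0.56; camera adjusted p = 0.856). Both eri-6 (−3.95, SE 0.11) and sid-1 (−3.02, SE 0.15) fell. Transgene part genes had 3 higher and 1 lower of 5 (median 0.58; camera adjusted p = 0.109), where tbb-2, a tubulin gene, was at 0.69 (SE 0.16). The counts of these 7 lists were the same adjusted over the list alone. Of the neuron genes, egl-21 (−3.60, SE 0.38), ida-1 and snb-1 (−1.30, SE 0.33) fell and unc-17, with 1 read against 3, did not pass.

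Among genes that rose, nep-2, a neprilysin gene on chromosome II, had 15 reads against 3, a ratio of 10.6 (counting interval 2.99 to 57.0), which did not pass without rde-3 mut-16(DE6R) library 2 (3.02 on the log2 scale). The regulator of G protein signalling gene rgs-3 (3.17, SE 0.58) and szy-4 (2.40, SE 0.24) rose as well. Reads fell to 0 at fbxa-125 from 228, at least 36-fold lower, at R193.3 from 101, at least 15.9-fold lower, and at the neuronal gene ida-1 from 89, at least 14.0-fold lower. Reads at mut-16 rose from 7 to 15 (2.12, SE 0.64; edgeR's quasi-likelihood test with Benjamini-Hochberg adjusted p = 3.46e-03), a call absent in DESeq2, without the filter on low counts, and without rde-3 mut-16(DE6R) library 1 (2.14) or 2 (2.11). Reads on mut-14 (0.74, SE 0.11), wago-1 (0.90, SE 0.11) and ppw-2 (0.26, SE 0.08) rose. The rise of ppw-2 did not pass without mut-16(DE6R) library 2 (0.26) or rde-3 mut-16(DE6R) library 1 (0.24), in DESeq2, or with library totals or mitochondrial reads, and turned with no filter. Neither prg-1 (0.03, SE 0.07) nor rde-1 (0.06, SE 0.14) passed. Both were below 0 with library totals and with mitochondrial reads, while prg-1 rose with upper quartiles (0.17) and both rose with totals without F56H9.8 (0.44 and 0.47). The median of all genes was −0.02, or −0.11, 0.39, −0.16 and 0.11 with library totals, totals without F56H9.8, mitochondrial reads and upper quartiles. The split of 877 and 1393 became 2052 and 1120 without F56H9.8 in the totals, 445 and 1486 with mitochondrial reads, 1284 and 1274 with upper quartiles, 143 and 1645 with no filter on low counts, and 217 and 988 in DESeq2. Germline division genes had between 4 higher, with mitochondrial reads, and 30, without F56H9.8 in the totals, where ribosomal protein genes had 23 higher and 1 lower, RNAi cofactor genes 9 and 6, Argonaute genes 9 and 2, and germ granule genes 10 and 2. With mitochondrial reads RNAi cofactor genes had 1 and 7 and Argonaute genes 3 and 3.

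**Figure D2:**
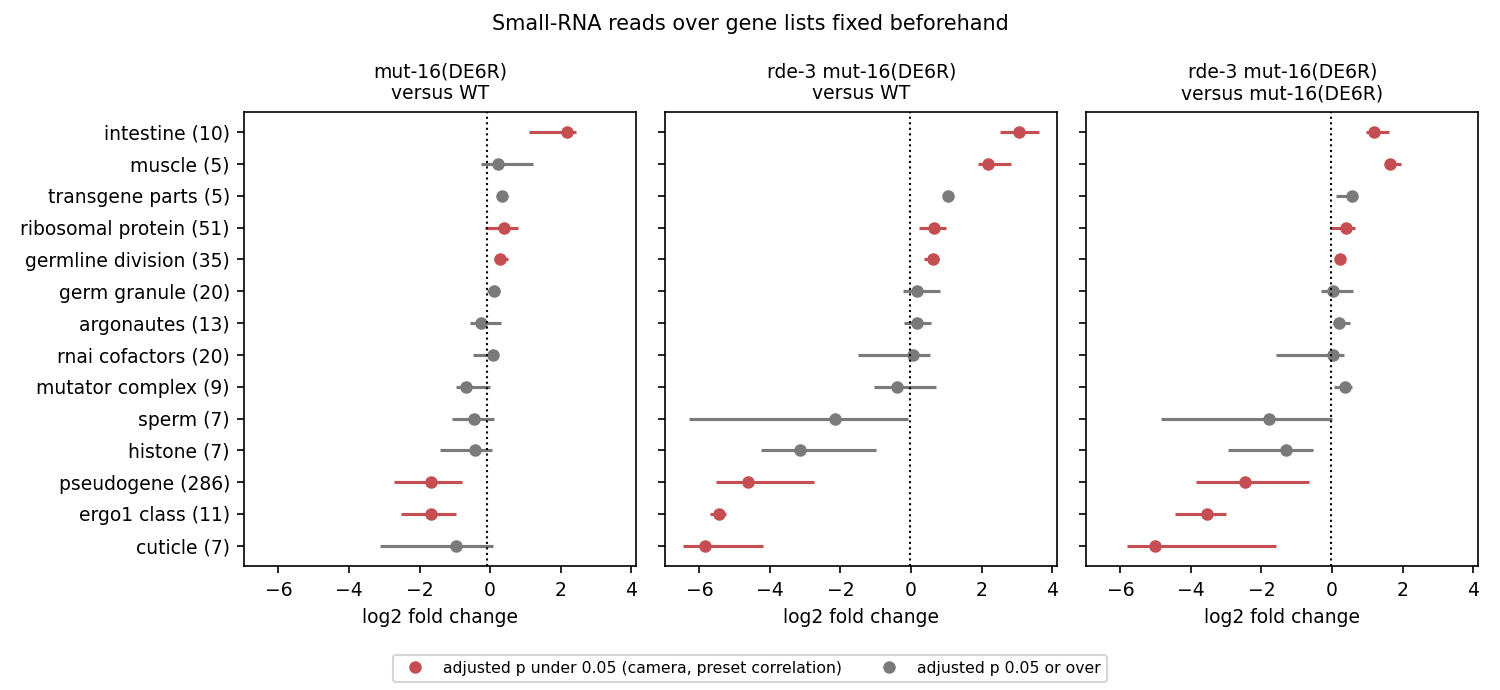
Median log2 fold change (dots) and 25th to 75th percentile (lines) of the tested genes of each list in the 3 comparisons, with the median of all genes as a dotted line, the number of tested genes in parentheses, and lists with a camera adjusted p under 0.05 in red. ERGO-1 targets had medians of −1.67, −5.45 and −3.56 and intestine genes 2.17, 3.06 and 1.20 from the first to the third comparison. Medians of the Argonaute, cuticle, histone, mutator complex and sperm lists turned sign with another scaling in the first comparison. So did those of the mutator complex list in the second and of the germ granule and RNAi cofactor lists in the third. That of the sperm list in the second turned without F56H9.8 in the totals, which also changed which genes were tested.

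Calls against the shared WT libraries overlapped. Both genotypes carry the mut-16(DE6R) allele as well, so an overlap above that of independent lists says little by itself. In the single and the double mutant, 803 genes rose in both and 1692 fell in both, against 314.4 and 737.4 for independent lists of the same sizes. Another 78 genes rose in mut-16(DE6R) and fell in rde-3 mut-16(DE6R), and 15 went the opposite way. The fold changes correlated across genes, which are not independent replicates, with r = 0.776, against 0.572 in 50 simulations of unchanged groups that shared the same controls, and their covariance was 3.30 against 0.0929, a difference of 3.20. In those simulations edgeR's quasi-likelihood test called 0 genes in the same direction in both at the adjusted threshold, and 57.8 on average at an unadjusted p under 0.05, where the data had 2649. The 2 control libraries were not split between the comparisons, since that would leave 1 library to each. Part of the excess over independent lists may therefore come from sharing them, although sharing alone gave a covariance of only 0.0929 in the simulations.

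The tethering strains were compared with the strain labelled as tethered wild type, which asks whether a protein brought to the transgene changes its small RNAs. Reads on the transgene were 163.5 ± 16.3 (SD, n = 2) in the tethered wild type. Tethered MUT-14, a DEAD-box helicase of the mutator complex, gave 2122.5 ± 121 reads (SD, n = 2), 13.0-fold more (log2 3.70, counting interval 12 to 15). Tethered MUT-16 gave 1041 ± 112 reads (SD, n = 2), 6.37-fold more (5.66 to 7.18), and the strain labelled MUT-16(ex773-1050) gave 2998 ± 245 (SD, n = 2), 18.3-fold more (16.4 to 20.6). The strain labelled MUT-16(de773-1050) gave 102.5 ± 9.19 reads (SD, n = 2), 0.627 times the control (0.524 to 0.749) and 10.2-fold fewer than tethered MUT-16, while MUT-16(ex773-1050) was 2.88-fold above MUT-16 (2.74 to 3.03). The labels do not spell out what de and ex stand for.

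Tethered PGL-3 and the tethered Argonautes gave between 0.486 and 1.11 times the reads of the control. PGL-3, a P granule scaffold, had 139.5 ± 2.12 reads (SD, n = 2), 0.853 times the control (0.725 to 1.00). The Piwi protein PRG-1 had 143.5 ± 27.6 (0.878, 0.746 to 1.03) and the Argonaute RDE-1, which takes up siRNAs from double-stranded RNA, had 182 ± 12.7 (1.11, 0.956 to 1.3; SD, n = 2 each). The secondary Argonautes WAGO-1 and WAGO-3 had 79.5 ± 12.0 and 108 ± 4.24 reads (SD, n = 2 each), 0.486 (0.400 to 0.589) and 0.661 (0.554 to 0.787) times the control. In 9 of the 11 comparisons the pairs of libraries did not overlap, which chance gives in 33.3% of comparisons of 2 against 2. Each of these 9 had an exact 2-sided permutation p of 0.333, the smallest this size allows, and PRG-1 and RDE-1 had 0.667. Over all 10 strains at once, a permutation test of the log2 reads gave p = 1e-05, the smallest that 100000 resamples can give, with a pooled SD of 0.149 on the log2 scale within strains.

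**Figure D3:**
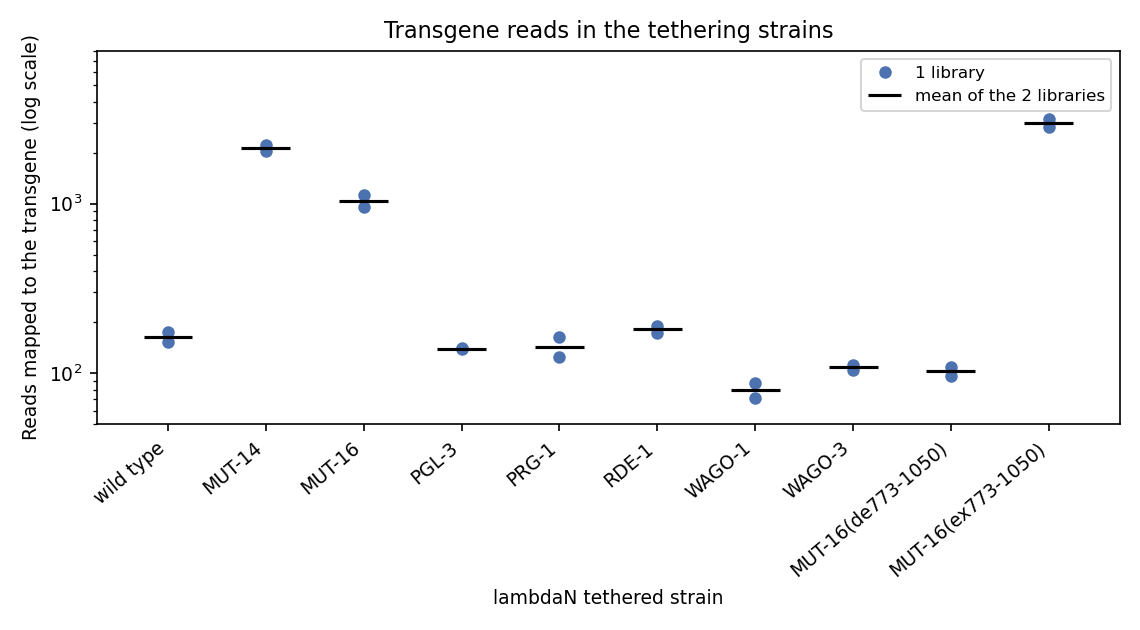
Reads mapped to the transgene (log scale) in the 2 libraries of each tethered strain (points) and their mean (line). Library totals and scaling of these values are not given in the sources used here, and the MUT-14, MUT-16 and MUT-16(ex773-1050) strains lie above the 152 and 175 reads of the tethered wild type.

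Total reads of the tethered libraries are not given in the sources used here, and totals of the 6 untethered libraries spanned 3.05-fold, a range that 3 of the 9 strains exceeded against the control and 6 did not. Counting intervals cover counting error only, since reads amplified by PCR are not independent molecules. Summed over all strains, pairs differed by more than counting error, with a chi-square of 49.5 on 10 degrees of freedom (p = 3.31e-07). That sum takes the libraries of a pair as equally deep, so it does not tell unequal depth from other spread, nor speak for each strain.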

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

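Upper quartile factors, library totals without F56H9.8, scaling to mitochondrial reads, unsummed transcripts, the block and mitochondrial scaling of the overlap, and the alternatives for transgene reads and pseudogene shares were chosen after the data were seen. Of 133 named gene results, 103 kept their direction and their side of the threshold under every alternative run, 23 changed their side under at least 1 and 7 reversed. Totals of changed genes stayed within 1.5 times under all alternatives except DESeq2, which called 2053 in mut-16(DE6R) against WT and 1205 in rde-3 mut-16(DE6R) against mut-16(DE6R), where edgeR called 3117 and 2270; the cause was not tested. Leaving out each library gave 2375 to 3269 genes in mut-16(DE6R) against WT, 2824 to 3560 in rde-3 mut-16(DE6R) against WT and 1652 to 2067 between the mutants, where a lone library is assumed to vary like the other groups. Genes that rose then numbered 725 to 1085 where all libraries gave 1173, 1021 to 1266 against 1424, and 542 to 678 against 877. The overlap of calls was 1732 in DESeq2 and 3697 with library totals, against 2495.

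Named genes that reversed had log2 fold changes between −0.25 and 0.26 except mut-16 (−0.96), and the cause was not tested. In mut-16(DE6R) against WT, mut-16 was at 0.19 with library totals, mut-14 at −0.023 in DESeq2 and −0.00097 with median ratios (−0.17 to 0.091 leaving out each library, below 0 without mut-16(DE6R) library 2 or WT library 1), and prg-1 at 0.95 with library totals, 0.10 with no filter, 0.15 with upper quartiles, 0.61 without F56H9.8 and 0.027 with mitochondrial reads. In rde-3 mut-16(DE6R) against WT, prg-1 was at 0.89 with library totals, 0.32 with upper quartiles and 1.04 without F56H9.8. Between the mutants, prg-1 was at −0.0020 in DESeq2, −0.0010 with median ratios, −0.053 with library totals, −0.26 with no filter, −0.099 with mitochondrial reads, −0.013 in a fit of 2 groups and −0.014 to 0.088 leaving out each library, below 0 without rde-3 mut-16(DE6R) library 1. There rde-1 was at −0.0011 in DESeq2, −0.024 with library totals, −0.25 with no filter, −0.087 with mitochondrial reads and −0.075 to 0.18 leaving out each library, below 0 without library 2 of either group, and ppw-2 at −0.032 with no filter.

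Of the 42 list tests, 19 passed with the preset correlation, 0 with an estimated correlation (10 at an unadjusted p under 0.05) and 31 with fry, which tests another hypothesis. The estimated correlation leaves camera only 3 degrees of freedom, which by itself raises its p-values. Directions reversed in fry for Argonaute genes in mut-16(DE6R) against WT (adjusted p = 0.155, range over alternatives 0.126 to 0.822), for RNAi cofactor genes in all 3 comparisons (0.802, 0.0226 and 0.0252 in the order mut-16(DE6R) against WT, rde-3 mut-16(DE6R) against WT and between the mutants, with ranges of 0.116 to 0.802, 0.0226 to 0.793 and 0.0252 to 0.978) and for mutator complex genes in rde-3 mut-16(DE6R) against WT (0.0559, range 0.0559 to 0.838), and with library totals for mutator complex genes in mut-16(DE6R) against WT (0.98, range 0.00923 to 0.98). Scaling to mitochondrial reads changed none of the 42. With geometric means or a library left out, all 55 transgene log2 ratios moved by less than the spread between libraries. Leaving out 1 of 2 libraries moves their mean by less than their SD at nearly any spread, so this outcome could hardly differ. It is no sign of robustness. Ratios of single libraries crossed 1 for PRG-1 (0.709 to 1.07) and RDE-1 (0.989 to 1.26). Pseudogene shares of all reads were 8.65%, 6.00% and 1.02%.

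Replicate numbers did not pair the libraries: same-numbered libraries correlated at 0.0062, 0.030 and 0.0071 in their deviations over 2138 genes. With the replicate number as a block, 3025, 3396 and 2203 genes changed in the 3 comparisons and 2434 overlapped, 19 lists passed, and among named genes only the call of rpl-18 between the mutants was lost. Alternatives listed for genome-wide tests of the tethered strains were not run, since gene counts of those libraries were not analysed here. Small changes were recovered least at the depth and number of libraries at hand, which were not varied: at 1.5-fold, 42% of simulated changes in 4744 genes were recovered in mut-16(DE6R) against WT, 30% in 4776 genes in rde-3 mut-16(DE6R) against WT and 28% in 4753 genes between the mutants.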

Other observations

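Of the tests here, those of gene families, of dilution with mitochondrial reads and of the depth of the tethered libraries were chosen only after the result was seen. Families of genes with a shared name stem were compared with all tested genes by Fisher's exact test, with Benjamini-Hochberg adjustment over 210 tests of 35 families. Reads fell at 28 of 40 F-box genes named fbxa in mut-16(DE6R) against WT (adjusted p = 3.88e-04 by Fisher's exact test) and at 32 of 40 in rde-3 mut-16(DE6R) against WT (1.36e-05), with a median of −1.67 on the log2 scale in the former. All 15 genes named fbxb fell in both (2.87e-05 and 3.28e-05), with medians of −3.38 and −5.52. The bath genes, which encode proteins with BTB and MATH domains, fell in 18 of 23 cases in mut-16(DE6R) against WT (1.31e-03), and 15 of 22 nuclear hormone receptor genes named nhr fell there too (0.0163). In the other direction, 15 of 18 nuclear pore genes named npp (4.56e-05) and 11 of 12 splicing factor genes named prp (1.81e-04) rose in rde-3 mut-16(DE6R) against WT, with medians of 0.72 and 0.84. The signs of these family medians held under all 6 scalings, but with library totals in mut-16(DE6R) against WT the genes lower and higher were 10 and 5 for bath (median −0.12), 12 and 7 for nhr, and 21 and 12 for fbxa. Copies within these families are similar, so reads shared between them are open.

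A group of 241 genes gained reads in mut-16(DE6R) against WT and lost them in rde-3 mut-16(DE6R) against mut-16(DE6R). Of the 235 with a chromosome, 125 lay on X (53.2%, exact interval 46.6 to 59.7), against 8.30% of 5239 tested genes. Tested genes on X did not gain reads as a whole in mut-16(DE6R) against WT: of 435, 153 rose (35.2%) and 175 fell (40.2%). On single autosomes 18.5% to 22.1% rose there. Scaling moved the size of this group from 235 up to 551 genes with library totals, of which 36.5% lay on X, and to 320 with mitochondrial reads, with 46.9%. In rde-3 mut-16(DE6R) against WT, 78 of the 241 were lower, 138 did not pass and 25 were higher. On X, glit-1, a gliotactin homolog, had 895 ± 52.5 CPM in WT, 1093 ± 15.9 in mut-16(DE6R) and 21.4 ± 4.13 in rde-3 mut-16(DE6R) (SD, n = 2 each), while F23A7.5 had 2271 ± 40.7, 3646 ± 86.2 and 2840 ± 170. These 2 genes and the pattern itself were picked after their values were seen.

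Scaling between libraries was tested as the cause of this excess on X. The lower limit of the share on X was 32.5% or more under all 6 scalings, a result taken beforehand as against it. A scaling factor shifts genes on X and elsewhere alike, however. Between the mutants 73.6% of tested genes on X fell, against 18.3% to 25.6% on single autosomes. An excess on X was thus likely under any scaling, so this outcome decides nothing. Low read levels in WT were argued against: of 10000 lists of genes matched on WT level the highest held 51 genes on X. This gives 1e-04, the smallest share this number of lists can give. It speaks to WT level alone, since the lists were not matched on the fall between the mutants. A candidate explanation, as a hypothesis, is that reads gained on X in mut-16(DE6R) need rde-3. Among genes that rose in mut-16(DE6R), 81.7% of those on X and 10.9% elsewhere fell when rde-3 was mutated too, an odds ratio of 36.4 (22.8 to 59.8), but the fall is part of how the 241 genes were chosen, so this value decides nothing. Genes on X that did not rise in mut-16(DE6R) fell as well, 69.1% against 23.7% elsewhere, so a loss on X that has nothing to do with the gain stays open.

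Reads at 10 of 10 tested intestine and 4 of 5 tested muscle genes were higher in rde-3 mut-16(DE6R) than in WT. Some of these genes passed the filter only through mutant libraries, so part of this count was set in advance. One dilution factor shared with mitochondrial reads was argued against, since after scaling to these the 25th percentile of log2 over the 15 tested intestine and muscle genes was 2.32. Mitochondrial genes had a median of −0.05 with TMM, and scaling to them moved the median of all genes only from −0.03 to 0.10. The outcome could thus be foreseen. It speaks only against a factor that raised mitochondrial reads equally, not against dilution in general. A larger share of somatic tissue in the double mutant could raise such reads: among genes under 5 CPM in WT, summed reads rose 7.09-fold for intestine (4.64 to 11.3) and 2.94-fold for muscle (2.03 to 4.34), but were 0.955 times WT for cuticle (0.737 to 1.24) and 0.379 times for neuron genes (0.107 to 1.11). The lowest upper limit, 1.11 for neuron genes, lay under the 2-fold rise set beforehand, a result taken beforehand as against this explanation. Tested cuticle genes fell with a median of −5.85 (−4.73 with genes at 0 at their bound). These include genes with more reads in WT, such as col-111 with 225. Whether genes under 5 CPM lost rde-3-dependent reads too was not tested, and such a loss could hide a rise, so the bound does not decide. A larger share of somatic tissue and a direct effect of the mutations, which was not tested, cannot be told apart here. Whether strand was used in counting is not given, so whether these reads are small RNAs made on these genes is open too.

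Transgene reads of the MUT-14, MUT-16 and MUT-16(ex773-1050) strains were above those of the tethered wild type, by 6.37-fold at the lowest. Different library depth could give part of such a ratio, and the totals of these libraries, which would decide, are not given in the sources used here. Totals of the untethered libraries spanned 3.05-fold, while libraries of a tethered pair differed in transgene reads by at most 1.31-fold, against 2.53-fold in totals within an untethered pair. Depth and an effect of the tethered protein, the biological difference that the design names, cannot be told apart from these values.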
